A study of Homo sapiens with 40 samples.

How the data were processed

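The data were 40 text files from Agilent one-colour arrays, 1 per sample, with their labels and the authors' table of values. Total RNA had been isolated with a column kit, checked on a Bioanalyzer and labelled with Cy3-CTP, per the labels. The file headers name Feature Extraction 10.7.3.1 with the protocol GE1_107_Sep09, while the submitters' processing notes name 10.7.7.1. The main value was the processed signal, an intensity on a linear scale, per the file headers. The software had subtracted background and removed a multiplicative trend within each array, with no step between arrays. Raw medians of signal and background are intensity as well, per the file headers. The authors' table of values is in log2. Its sorted columns were equal to within 0.0049 and all 40 column medians were 6.90, as quantile normalization between arrays gives. Its correlation with the log2 processed signal was 0.985 to 1.00. The sources say no more of how it was made.

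The files hold 43376 spots of 41000 probes. Spots that the software called non-uniform or population outliers were left out on that array, which affected 780 tested genes. Spots of the same probe were averaged on the log2 scale. The log2 signal was reduced by the array's own 75th percentile, so values are log2 relative to that percentile, from intensity per the file headers. A probe was tested if it was well above background on at least 3 of the 40 arrays, which left 33098 probes. Gene symbols came from matching the RefSeq accession of each probe to a list of human RefSeq genes on GRCh38.p14. Probe coordinates in the files are on hg18, so none are given. Of the probes, 25398 matched a symbol and 15602 did not, 787 of them for RefSeq mRNAs. Probes without a symbol were kept under their own names. For each symbol the probe with the highest mean log2 signal represented the gene, which gave 26256 genes, 15160 with a symbol. Members of the lists that had no symbol match were ACER2, CYFIP2, PERP, NHERF1, NFKB2, IFI27, UBE2C, NOP16, JUND, SLC3A2 and COL1A1. Members that were not above background often enough were TRIM22, CXCL1, CXCL8, VCAM1, CSF2, SAA1, CDH2, ZEB1, LUM, PDGFRB, PECAM1 and LYZ. RELA, which was to be named in each comparison, had no match.

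Groups were those of the labels. For 1 array of doxorubicin with 100 nM estradiol the title gives replicate 2 and another field replicate 1, and the title was used. The 11 groups and 40 arrays were fitted in 1 model with limma 3.58.1 in R 4.3.3, without covariates, with moderated variances (eBayes, no trend) and two-sided tests. P-values were adjusted over all genes tested by Benjamini and Hochberg, with a threshold of 0.05. Departure from additivity was the change with both agents minus the sum of the changes with each. A gene was beyond both when the combination differed from each agent in the same direction with both adjusted p under 0.05. The scan day, taken from the file headers, entered as a fixed block in an alternative, and each comparison was also made within single scan days.

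The 13 lists were fixed in advance from general knowledge: p53 targets, estrogen-induced, estrogen-repressed, NF-kB targets, interferon response, DNA replication, mitosis, ribosome biogenesis, immediate early, ATF4 and ER stress, mesenchymal and migration, epithelial, and stromal and blood cell genes. Each was tested against all other genes with camera, with the preset correlation of 0.01 and with a correlation estimated from the data, adjusted over the 13 lists within a comparison. A count adjusted over the list alone uses the p-values of its members only.

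Named genes followed a rule. Against mock these were, among genes measured in both groups, with adjusted p under 0.05 and with all treated arrays beyond all control arrays, up to 8 with the largest rises and 6 with the largest falls. For an added agent, for the 2 drugs and for the 2 estradiol doses they were up to 6 each way. For departures from additivity they were the 6 most positive and 6 most negative. For genes beyond both, they were the 6 each way with the largest smaller change. Up to 4 members of each list with the smallest adjusted p were added, and CDKN1A, MDM2, GDF15, TFF1, PGR, GREB1, NFKBIA, TNFAIP3, ICAM1, TP53 and ESR1 always. Genes without a named symbol were passed over. The groups, comparisons, lists, naming rule and alternatives were chosen before the data were examined, except where said.

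Quality values came from the files. The 75th percentile of the signal ranged over 873 to 1942 on scan day 1, 767 to 1244 on day 2 and 537 to 1203 on day 3, and the 5th percentile over 3.35 to 5.44, 15.6 to 21.1 and 3.35 to 7.76. The lowest correlation between replicates of a group across genes was 0.954 and the highest 0.991. Whether equal replicate numbers pair cultures was checked by correlating deviations from group means across genes. All these correlations exceeded 0.1 in 5 comparisons, doxorubicin (0.37 to 0.71), 5-fluorouracil (0.23 to 0.38) and 100 nM estradiol (0.40 to 0.50) against mock, and 100 nM estradiol added to doxorubicin (0.30 to 0.49) and to 5-fluorouracil (0.26 to 0.69). There the numbers also match the scan days. They were not taken as pairs in the 8 other comparisons. Arrays on the same slide correlated by 0.43.

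Simulated data with 200 changed genes tested the model. For 5-fluorouracil against mock it recovered 2.99, 32.8 and 84.8% of genes changed by 0.5, 1 and 2 log2 units. For the departure of doxorubicin and TNF it recovered 0, 13.4 and 65.2%. It called 1 to 6 unchanged genes. More genes passed on real arrays (8155 and 385), so neither misses nor false calls are bounded there. Overlaps of 2 comparisons with the same controls were set against 20 simulated draws and separate mock arrays.

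The alternatives were the scan day, slide or replicate number as a block, quantile normalization, the authors' table, raw medians with normexp background correction and an offset of 50, no filter, a filter of 20 arrays, the mean of all probes of a gene, a model of the compared groups alone, and leaving out each array. Random regroupings numbered at most 100 per result and random lists 10000. The R package data.table, version 1.17.8, held the values, and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The scanned images were not used here.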

Results

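MCF7 cells, a human breast cancer line that carries functional p53 and the estrogen receptor, were treated for 10 h with agents that engage 3 transcription factors. Doxorubicin at 1.5 µM and 5-fluorouracil at 375 µM damage DNA or block nucleotide supply and activate p53. The hormone 17β-estradiol at 1 or 100 nM activates the estrogen receptor, and the cytokine TNF at 5 ng/ml activates NF-kB. Cells had been plated 24 h before in medium with 10% charcoal-treated serum, which holds little estrogen. Total RNA from 40 cultures was hybridized to 40 one-colour Agilent arrays with 41000 probes. The 11 groups were mock treatment (n = 6), doxorubicin (n = 7), and 9 groups of 3 arrays each. These were 5-fluorouracil, estradiol at each dose, TNF, doxorubicin with estradiol at each dose, 5-fluorouracil with 100 nM estradiol, doxorubicin with TNF, and doxorubicin with 1 nM estradiol and TNF. The purpose the labels state was to compare each combination with its agents given singly and so find transcripts that depend on more than 1 of the 3 factors.

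The arrays had been scanned on 3 days, with 12, 8 and 20 arrays. Mock arrays fell 2, 2 and 2 across the scan days and doxorubicin arrays 2, 2 and 3. The groups with 5-fluorouracil or 100 nM estradiol were scanned on days 1 and 2, and the groups with 1 nM estradiol or TNF on day 3. The share of probes well above background was 72.3 to 77% on day 1, 47.4 to 54.8% on day 2 and 58.9 to 68.8% on day 3. Hence each count of changed genes is given also with the scan day as a block and within single scan days. The number of arrays limits the precision of every value, and no spot was saturated. Of 26256 genes tested, 15160 had a symbol. Values are log2 signal relative to the array's 75th percentile, and changes are log2 differences ± standard error from limma with two-sided tests. The p-values rest on the spread between arrays, labelled biological replicates, with scan day and slide included and pairs ignored. A gene counted as changed when its adjusted p was under 0.05, and "rose" and "fell" are used for such genes. Where a gene was not well above background on any array of a group, its direction and adjusted p are given without a fold. For each gene named as having risen or fallen between 2 groups, every array of one group lay beyond every array of the other, except for CDKN1A with TNF, ICAM1 with 100 nM estradiol, FOSL1 with 5-fluorouracil, GADD45A with estradiol added to 5-fluorouracil, and CD79A, CXCL12, ICAM1, MDM2, NFKBIA, TNFAIP3 and VIM with doxorubicin.

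The median change of all genes was not 0 in several comparisons, shifting the balance of higher and lower genes. It was 0.29 for 5-fluorouracil, 0.18 for doxorubicin, −0.19 for TNF and −0.16 for 1 nM estradiol, each against mock, and −0.18 for doxorubicin against 5-fluorouracil. Among the combinations it was −0.14 for TNF and −0.13 for 1 nM estradiol added to doxorubicin. The estradiol doses differed by 0.10, and the departure from additivity of 1 nM estradiol and TNF in doxorubicin had a median of 0.10. With normexp background correction of the raw median signals, a setting tried after the data were seen, the sign turned without passing the threshold for some genes named here. They were VIM, MDM2, TNFAIP3 and ICAM1 with doxorubicin, VEGFD, FOSL1 and MDM2 with 5-fluorouracil, and ICAM1 and VWF with 100 nM estradiol.

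**Figure D1:**
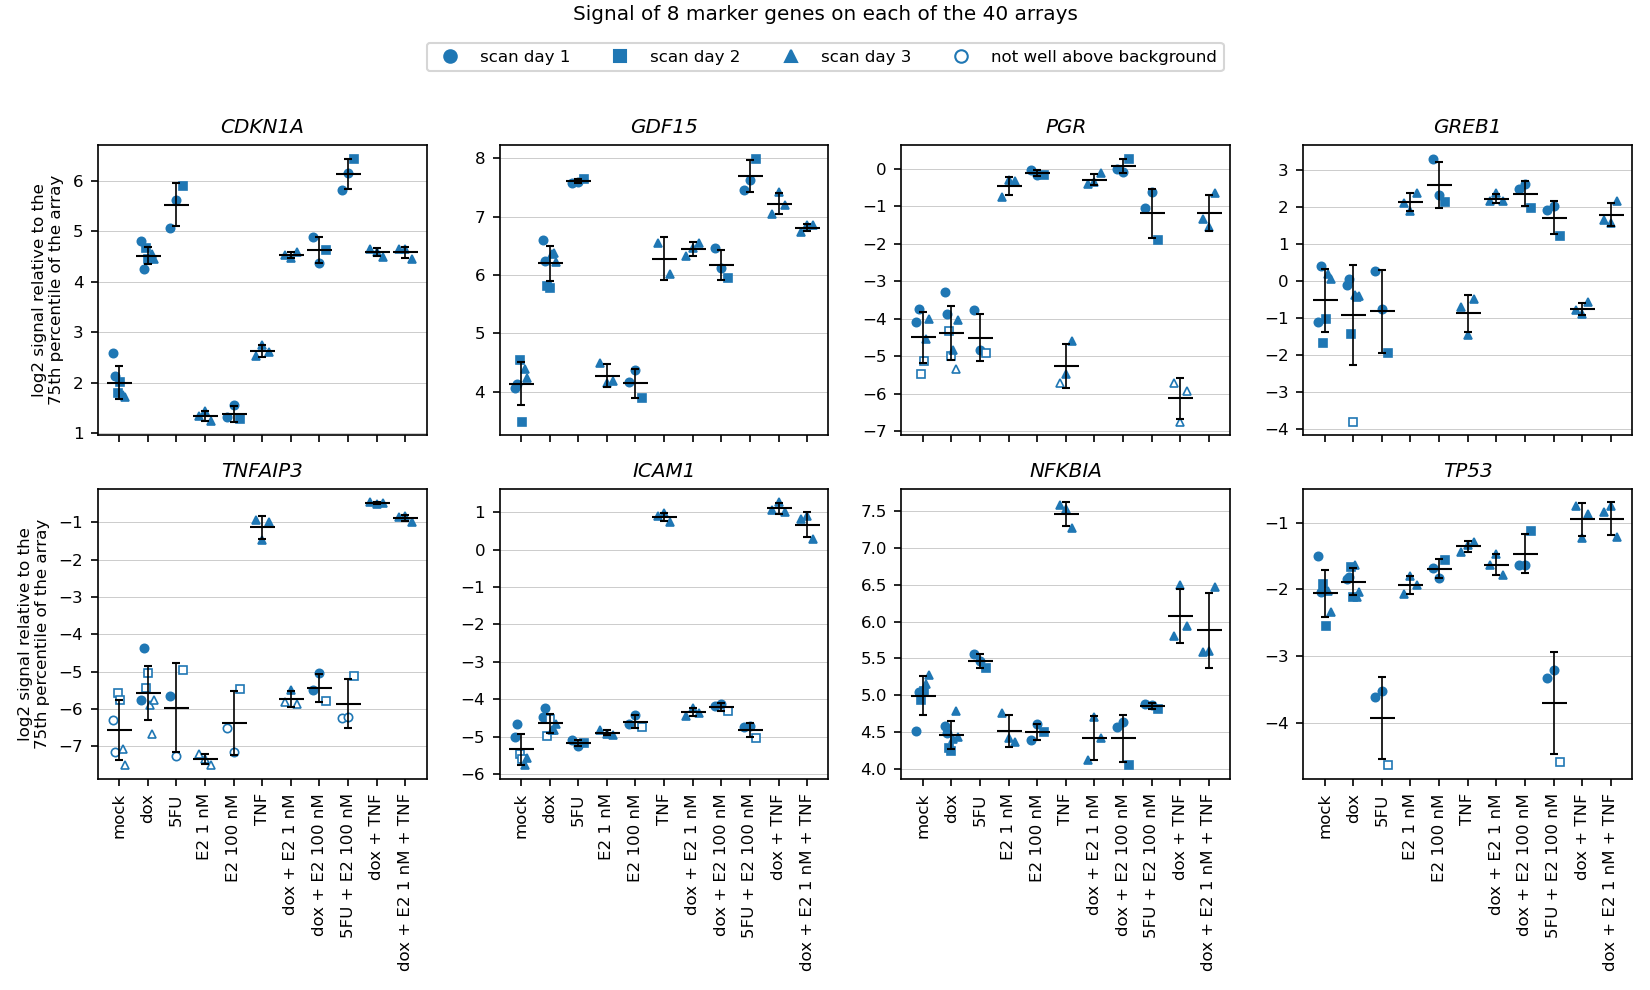
Log2 signal relative to the array's 75th percentile (y axis) for 8 genes in the 11 treatment groups (x axis). Points are arrays with the marker shape giving the scan day and open markers not well above background, bars are mean ± SD, and spots called outliers by the scanning software are left out; CDKN1A averaged 2.01 in mock, 4.52 with doxorubicin and 5.52 with 5-fluorouracil.

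Doxorubicin was compared with mock treatment (n = 7 and 6) to find the response to DNA damage. Transcripts of p53 targets rose. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 5.71-fold (2.51 ± 0.13, adjusted p = 1.3e-15), from 2.01 ± 0.33 (SD) in mock to 4.52 ± 0.18. The death receptor genes FAS and TNFRSF10B rose 14.8-fold (3.89 ± 0.19, adjusted p = 1.5e-16) and 13-fold (3.70 ± 0.13, adjusted p = 2.6e-20), and the stress kinase gene PLK3 rose 25.7-fold (4.68 ± 0.15). GDF15, which encodes a secreted stress cytokine, rose 4.15-fold (2.05 ± 0.15), while MDM2, whose product degrades p53, rose 1.83-fold (0.87 ± 0.21, adjusted p = 0.0012). MYC, a driver of cell growth, fell 8.74-fold (−3.13 ± 0.25, adjusted p = 1.5e-11), and the mitotic kinase gene PLK1 fell 4.63-fold (−2.21 ± 0.12).

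The largest rises among measured genes with all 7 treated arrays above all 6 mock arrays were in INSYN2A, a synaptic factor gene (109-fold, 6.76 ± 0.23), and NPTX1, a pentraxin gene (34.6-fold, 5.11 ± 0.38). ARC followed at 33.8-fold, and then RGCC at 28.7-fold, PLK3 as given above, DIO3 at 24.8-fold, DUSP5 at 22.8-fold and ACTA1 at 21.8-fold. MAB21L4 fell most (13.1-fold, −3.72 ± 0.22), followed by TP63, a gene of the p53 family (11.4-fold). SLC25A12, DOK7 and ZNF112 fell 9.18-fold, 9.03-fold and 8.90-fold. TP53 itself was 0.17 ± 0.19 higher (adjusted p = 0.51), and ESR1, which encodes the estrogen receptor, fell (−0.54 ± 0.11, adjusted p = 0.00024). NFKBIA, the gene of the NF-kB inhibitor, fell (−0.54 ± 0.15, adjusted p = 0.0041). ICAM1, which encodes an adhesion molecule, rose 1.63-fold. TNFAIP3, a gene of an NF-kB brake that was not well above background on any mock array, was higher (adjusted p = 0.022). PGR and GREB1, which estrogen induces, were 0.11 higher and 0.40 lower (adjusted p = 0.81 and 0.51), and the probes of each gene disagreed in sign.

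Of 40 p53 targets tested, 38 rose, 1 fell and 1 did not pass (39 and 1 adjusted over the list alone), with a median of 1.53 and within-day medians of 1.54, 1.66 and 1.46. Of 24 mitosis genes, 21 fell (22 adjusted over the list alone), with a median of −0.88, and BUB1B and CCNA2 fell 6.54-fold and 4.11-fold. Both list tests (camera) passed with a preset correlation and with an estimated one (adjusted p = 7.1e-06 and 0.00045 with an estimated correlation). Of 26 DNA replication genes, 3 rose and 13 fell (4 and 14 adjusted over the list alone), with a median of −0.40. MCM10 fell 2.82-fold, while PCNA and CCNE1 rose 3.07-fold and 2.83-fold. Of 36 NF-kB targets, 13 rose and 3 fell (14 and 3 adjusted over the list alone, median 0.38). Among them IRF1 rose 3.67-fold and NFKBIE rose 3.01-fold. Of 19 immediate early genes, 10 rose and 4 fell, before and after adjustment over the list alone, and ATF3 rose 16.7-fold and FOS 9.70-fold. Of 11 estrogen-repressed genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone, median −0.69). The tests of these 4 lists passed with the preset correlation but not with an estimated one (adjusted p = 0.43, 0.12, 0.11 and 0.063 with an estimated correlation).

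The remaining lists had no passing test. Of 35 estrogen-induced genes, 9 rose and 8 fell (11 and 8 adjusted over the list alone), with CXCL12 up 3.61-fold and RARA down 5.45-fold, though the probes of RARA disagreed in sign. Its median was 0.08 but its mean −0.04. Of 23 interferon response genes, 7 rose and 4 fell (7 and 4 adjusted over the list alone), with ISG15 up 2.2-fold and MX1 down 3.14-fold. Of 19 ribosome biogenesis genes, 4 rose and 9 fell (5 and 9 adjusted over the list alone), and POLR1B fell 3.73-fold. Of 16 ATF4 and ER stress genes, 4 rose and 6 fell (5 and 6 adjusted over the list alone). Among mesenchymal genes 2 of 19 rose and 1 fell, with VIM up 0.58, and among epithelial genes 4 of 17 rose and 4 fell, with CLDN4 down 1.38 log2 units. Of 11 stromal and blood cell genes, 1 rose, CD79A (1.82-fold, adjusted p = 0.0077). In all, 10051 genes changed, 5689 higher and 4362 lower. With quantile normalization between the arrays the balance turned, with 4186 higher and 5001 lower. A block on the scan day gave 12683 genes, of which 10049 were among the 10051. Within the scan days 1467, 1579 and 8077 passed.

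5-Fluorouracil was compared with mock (n = 3 and 6) to find the response to a second p53-activating drug. CDKN1A rose 11.4-fold (3.52 ± 0.17, adjusted p = 2.5e-16), GDF15 11-fold (3.46 ± 0.19, adjusted p = 7.8e-15) and FAS 15.0-fold (3.90 ± 0.24). MDM2 rose 5.44-fold (2.44 ± 0.27, adjusted p = 1.3e-08), and GADD45A, a DNA damage response gene, rose 9.55-fold (3.25 ± 0.21). The transcript of TP53 fell 3.65-fold (−1.87 ± 0.24, adjusted p = 3.8e-07), from −2.06 ± 0.36 (SD) to −3.93 ± 0.62, as measured by a single probe. The gene of topoisomerase 2-alpha, TOP2A, fell 5.70-fold (−2.51 ± 0.20, adjusted p = 3.1e-11).

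Among the largest rises were those in SERPINC1, which encodes antithrombin (55.2-fold, 5.79 ± 0.36), the phosphatase gene INPP5D (12.5-fold) and VEGFD (11.7-fold). The largest falls were in ABLIM2 (11.1-fold, −3.47 ± 0.24), PRDM16 (10.2-fold), LDLRAD4 (9.45-fold) and OSBPL5 (8.73-fold), and in SHANK2 and NFATC1, whose probes disagreed in sign. ESR1 fell by its brightest probe (−0.69, adjusted p = 0.00037), but its probes disagreed in sign and their mean change was 0.00. TFF1, an estrogen target, rose 1.60-fold (adjusted p = 0.0031). NFKBIA was 0.47 and ICAM1 0.17 higher (adjusted p = 0.057 and 0.47), where ICAM1 fell with quantile normalization (−0.61), and PGR was −0.01 and GREB1 −0.29 from mock, again with probes of both signs.

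Of the 40 p53 targets, 33 rose and 1 fell (33 and 3 adjusted over the list alone), with a median of 1.33, and of the 24 mitosis genes 22 fell, before and after adjustment over the list alone, with a median of −1.48. Both list tests passed also with an estimated correlation (adjusted p = 0.00019 and 4.3e-05). HMMR, KIF20A and DLGAP5, genes of spindle proteins, fell 4.24-fold, 3.99-fold and 3.90-fold. Among 26 DNA replication genes 3 rose and 7 fell (3 and 8 adjusted over the list alone, median −0.23), with PCNA up 2.32-fold and MCM3 down 3.70-fold. This test passed with the preset correlation (adjusted p = 0.57 with an estimated correlation) and not with the scan day as a block. Of 19 immediate early genes 10 rose (11 adjusted over the list alone), among them FOSL1 (2.75-fold) and JUNB (2.31-fold), and the test did not hold otherwise (adjusted p = 0.15 with an estimated correlation). Among NF-kB targets 6 rose and 1 fell (6 and 1 adjusted over the list alone), with PLAU up 3.35-fold. Among estrogen-induced genes 6 rose and 1 fell (6 and 0 adjusted over the list alone), and among estrogen-repressed genes 1 rose and 2 fell. Interferon response genes had 2 higher and 3 lower, ribosome biogenesis genes 2 and 2 (2 and 1 adjusted over the list alone), and ATF4 genes 4 and 1 (5 and 3 adjusted over the list alone). Epithelial genes had 7 higher and 2 lower (9 and 3 adjusted over the list alone), mesenchymal genes 4 and 2, and stromal genes 0 and 0. In all, 8155 genes changed, 4974 higher and 3181 lower, against 3424 higher and 4032 lower with quantile normalization. A block on the scan day gave 8558, 7293 of them shared, and within scan day 1 the number was 2547.

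Doxorubicin and 5-fluorouracil were then compared directly (n = 7 and 3) to see where 2 activators of p53 differ. Each of 4 p53 targets differed: CDKN1A was 2.00-fold lower with doxorubicin (−1.0 ± 0.17, adjusted p = 1.2e-05), MDM2 2.97-fold lower (−1.57 ± 0.26, adjusted p = 1.1e-05) and GDF15 2.65-fold lower (−1.41), while PLK3 was 5.63-fold higher (2.49 ± 0.19). TP53 was 4.11-fold higher with doxorubicin (2.04 ± 0.24, adjusted p = 2.3e-08) and MYC 6.48-fold lower (−2.70). INSYN2A (96.2-fold), NPTX1 (56.8-fold), DIO3 (28.1-fold), ARC (26.6-fold) and CCM2L (24.5-fold) were most in excess with doxorubicin. IL20, a cytokine gene (32.4-fold, −5.02 ± 0.62), TNFRSF11B, the gene of the decoy receptor osteoprotegerin (26.7-fold, −4.74 ± 0.34), and MAB21L4 (20.3-fold) were most in excess with 5-fluorouracil.

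Of p53 targets 15 were higher and 7 lower with doxorubicin (16 and 8 adjusted over the list alone), and of mitosis genes 9 and 3 (9 and 3 adjusted over the list alone), with TOP2A 3.97-fold higher. The tests of these 2 lists passed with the preset correlation and neither did otherwise (adjusted p = 0.92 with an estimated correlation for each). DNA replication genes had 7 higher and 7 lower, NF-kB targets 8 and 5, interferon response genes 4 and 4, immediate early genes 8 and 6 (9 and 8 adjusted over the list alone), ATF4 genes 5 and 5, and ribosome biogenesis genes 2 and 4. Estrogen-induced genes had 5 and 7 (5 and 8 adjusted over the list alone), estrogen-repressed genes 1 and 2, epithelial genes 2 and 6 (4 and 6 adjusted over the list alone), mesenchymal genes 2 and 2, and stromal genes 0 and 0. In all, 8466 genes differed, 3970 higher and 4496 lower with doxorubicin. Blocked by scan day, 8716 passed, and within scan day 1 the number was 4993. Against the same mock arrays, 2210 genes rose with both drugs (1078 for independent responses) and 1168 fell with both (528). Another 1006 went opposite ways (1516). The changes correlated across genes with r = 0.33, where simulated values with no effects and shared mock arrays gave 0.43. The covariance was 0.18 against 0.046 simulated, and 0.14 when each drug was set against different mock arrays, where 1116.5 genes rose with both on average (611.5 if independent).

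**Figure D2:**
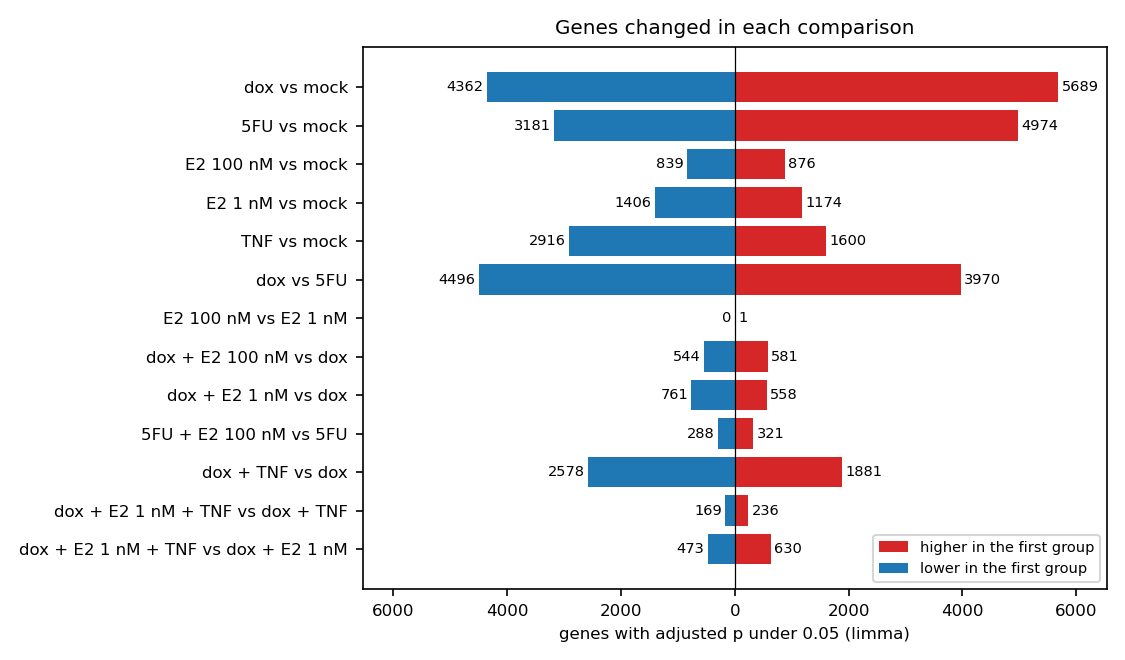
Number of genes with adjusted p under 0.05 (x axis) in 13 comparisons (y axis), with bars to the right for higher and to the left for lower in the first group. Counts run from 1 between the estradiol doses to 10051 for doxorubicin against mock.

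Estradiol was compared with mock at 100 nM and at 1 nM (n = 3 and 6 each) to find the response of the estrogen receptor. At both doses PGR, which encodes the progesterone receptor, rose, 20.7-fold at 100 nM (4.37 ± 0.39, adjusted p = 9.5e-10) and 16.4-fold at 1 nM (4.03 ± 0.39, adjusted p = 7.0e-09). GREB1, a growth regulator induced by estrogen, rose 8.74-fold (3.13 ± 0.56, adjusted p = 0.00024) and 6.29-fold (2.65 ± 0.56, adjusted p = 0.0015). MYC rose 3.19-fold and 2.81-fold, and genes of DNA replication rose, MCM2 by 2.13-fold and 2.69-fold and MCM10 by 2.51-fold and 2.92-fold. WNT11, a signalling ligand gene, fell 15.1-fold and 12.1-fold, and BMF, a pro-apoptotic gene, fell 7.90-fold and 10.3-fold. CDKN1A fell 1.54-fold (−0.62 ± 0.17, adjusted p = 0.021) and 1.58-fold (−0.66 ± 0.17, adjusted p = 0.011), the second of which did not pass with the scan day as a block (−0.52, adjusted p = 0.09).

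FGFBP2, a secreted binding protein gene, rose most at both doses (42.7-fold and 36.0-fold). PDZK1, a scaffold gene, rose 19.9-fold and 14.3-fold, CXCL12, a chemokine gene, 16.9-fold and 13.9-fold, and UGT2B11, a gene of steroid conjugation, 16.7-fold and 10.1-fold. UGT2B15, KLK10 and CXCL14 rose 14.5-fold, 13.5-fold and 13.4-fold at 100 nM, and SYNDIG1 15.1-fold at 1 nM. PSCA fell 8.74-fold and 8.46-fold. VAT1L (13.3-fold) and CYP1A1 (8.75-fold) were among the largest falls at 100 nM and VTCN1 (9.19-fold) at 1 nM. TFF1, already at 8.0 ± 0.23 (SD) in mock, was 0.24 and 0.16 higher (adjusted p = 0.54 and 0.58). ICAM1 rose 1.68-fold at 100 nM (adjusted p = 0.0073) and was 0.45 higher at 1 nM (adjusted p = 0.11).

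Of 35 estrogen-induced genes 29 rose at 100 nM (31 adjusted over the list alone, median 1.97) and 28 at 1 nM, where none fell (32 and 1 adjusted over the list alone, median 1.85). Of 11 estrogen-repressed genes 9 and 10 fell (11 each adjusted over the list alone), with medians of −1.75 and −1.73. EFNA1 fell 3.36-fold at 100 nM, and CCNG2 fell 2.72-fold and 3.42-fold. Among 26 DNA replication genes 15 and 20 rose (21 and 24 adjusted over the list alone), with medians of 0.93 and 1.05, and of 19 ribosome biogenesis genes 13 and 16 rose (16 and 17 adjusted over the list alone), with BOP1 up 2.21-fold and 2.46-fold. Of 23 interferon response genes 5 and 8 fell (7 and 10 adjusted over the list alone), with IRF9 down 2.66-fold and 2.46-fold. These 5 tests passed at both doses also with an estimated correlation (interferon response, adjusted p = 0.0049 and 0.0098). Among 40 p53 targets 2 rose and 7 fell at 100 nM (2 and 7 adjusted over the list alone) and 1 and 8 at 1 nM (1 and 9 adjusted over the list alone). Among them TP53INP1, a p53 cofactor gene, fell 5.96-fold and 6.33-fold and BTG2, an antiproliferative gene, fell 3.50-fold and 3.57-fold. The test of this list passed at 100 nM with the preset correlation (adjusted p = 0.05 with an estimated correlation) and not at 1 nM.

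Of 24 mitosis genes 0 changed at either dose, with limma and with the list alone, at medians of 0.08 and 0.09. Immediate early genes had 4 higher and 2 lower at 100 nM (4 and 5 adjusted over the list alone) and 3 and 5 at 1 nM (5 and 7 adjusted over the list alone), with FOS up 10.4-fold and 4.80-fold. NF-kB targets had 1 higher and 3 lower, then 1 and 2 (2 and 3 adjusted over the list alone). ATF4 genes had 0 higher and 1 lower (3 and 2 adjusted over the list alone), then 1 and 3. Mesenchymal genes had 2 and 2, then 1 and 1, and epithelial genes 0 and 0 (1 and 3 adjusted over the list alone), then 0 and 3. The stromal and blood cell list had 1 higher at each dose, VWF (2.74-fold and 2.61-fold). In all, 1715 genes changed at 100 nM, 876 higher and 839 lower, and 2580 at 1 nM, 1174 higher and 1406 lower, against 1354 higher and 1033 lower with quantile normalization. Blocked by scan day, 2340 and 2090 passed, of which 1632 and 1618 were shared. Within scan day 1 the 100 nM dose gave 291, and within scan day 3 the 1 nM dose gave 1912.

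The estradiol doses were compared directly (n = 3 each) to ask whether the higher dose did more. With limma 1 gene differed, the chemokine gene CXCL14, which was 7.40-fold higher at 100 nM (2.89 ± 0.42, adjusted p = 0.0029, −2.53 ± 0.51 against −5.42 ± 0.15), and 4292 genes had an unadjusted p under 0.05. Blocked by scan day, CXCL14 did not pass (2.04, adjusted p = 0.87) and 1 gene not well above background at either dose did (PFKFB1, named after its values were seen). The doses shared no scan day, so dose and scan day are linked through the mock and doxorubicin arrays alone. PGR and GREB1 were 0.34 ± 0.45 and 0.48 ± 0.64 higher at 100 nM (adjusted p = 0.85 and 0.86). No list had a changed member (adjusted over the list alone, 4 NF-kB targets, 3 immediate early genes and 4 stromal and blood cell genes were higher and 1 mesenchymal gene was lower). The test of DNA replication genes passed with the preset correlation (median −0.22, adjusted p = 0.55 with an estimated correlation), and with the block its median was 0.15. The test of ribosome biogenesis genes passed likewise (median −0.09, adjusted p = 0.55 with an estimated correlation). Both doses raised 706 genes (39.2 if independent) and lowered 654 (44.9), with 0 in opposite directions. The covariance of the changes was 0.124, against 0.046 simulated from the shared mock arrays and 0.079 with separate mock arrays.

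TNF was compared with mock (n = 3 and 6) to find the response of NF-kB. ICAM1 rose 74.4-fold (6.22 ± 0.18, adjusted p = 1.5e-22), from −5.34 ± 0.43 (SD) to 0.87 ± 0.12. NFKBIA rose 5.49-fold (2.46 ± 0.19, adjusted p = 1.3e-11), and TNFAIP3, not well above background in mock, was higher (adjusted p = 6.1e-11). LTB, which encodes lymphotoxin beta, rose 3140-fold (11.62 ± 0.50), and UBD, which encodes a ubiquitin-like protein, rose 961-fold (9.91 ± 0.63). SERPINA3, an acute-phase gene, rose 457-fold (8.84 ± 0.24, adjusted p = 2.9e-23). GDF15 rose 4.39-fold (2.14 ± 0.22), CDKN1A 1.54-fold (adjusted p = 0.01) and TP53 1.64-fold (adjusted p = 0.04).

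Other large rises were in S100A8 (280-fold), IL32 (203-fold), the apoptosis inhibitor gene BIRC3 (190-fold), S100A9 (136-fold) and the complement gene CFB (124-fold). CDH18 fell most (14.0-fold, −3.81), followed by SRARP (10.0-fold), KCNJ8 (8.70-fold) and PMP22 (7.91-fold). ESR1 fell (−0.52, adjusted p = 0.01), and PGR and GREB1 were 0.76 and 0.35 lower (adjusted p = 0.17 and 0.7). Of 36 NF-kB targets 28 rose and none fell, before and after adjustment over the list alone, with a median of 1.47. Of 23 interferon response genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.50. PSMB9 and TAP1, genes of antigen processing, rose 10.4-fold and 6.08-fold, and the chemokine gene CXCL10, not well above background in mock, was higher (adjusted p = 6.9e-06). Of 19 ribosome biogenesis genes 12 rose (16 adjusted over the list alone, median 0.63). Of 19 immediate early genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), and of 11 estrogen-repressed genes 1 rose and 7 fell (1 and 7 adjusted over the list alone). These 5 tests passed also with an estimated correlation (estrogen-repressed, adjusted p = 0.018).

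Among 40 p53 targets 12 rose and 5 fell (12 and 6 adjusted over the list alone), with GADD45A up 6.56-fold and TNFRSF10B up 3.29-fold. Of 16 ATF4 genes 5 rose, before and after adjustment over the list alone, and SLC7A11, a cystine transporter gene, rose 3.44-fold. Of 19 mesenchymal genes 4 rose (5 higher and 1 lower adjusted over the list alone). The tests of these 3 lists passed with the preset correlation (adjusted p = 0.061 with an estimated correlation for each). Among 26 DNA replication genes 1 rose and 4 fell (1 and 7 adjusted over the list alone, median −0.45), a call that ended without the preset value (adjusted p = 0.49 with an estimated correlation, and 0.042 with the scan day as a block). Among 35 estrogen-induced genes 6 rose and 7 fell (9 and 8 adjusted over the list alone). Among epithelial genes 1 rose and 3 fell, among mitosis genes 1 fell, and VWF rose 4.39-fold as the 1 stromal and blood cell gene. In all, 4516 genes changed, 1600 higher and 2916 lower, against 1690 higher and 1604 lower with quantile normalization. In the fit with a scan day block 3196 passed, 2661 of them shared, and within scan day 3 the number was 2945. Doxorubicin and TNF both raised 536 genes (347 if independent) and both lowered 781 (484), and 739 went opposite ways (898). The covariance was 0.050, near the 0.046 that shared mock arrays gave in simulation, and 0.0051 with separate mock arrays.

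**Figure D3:**
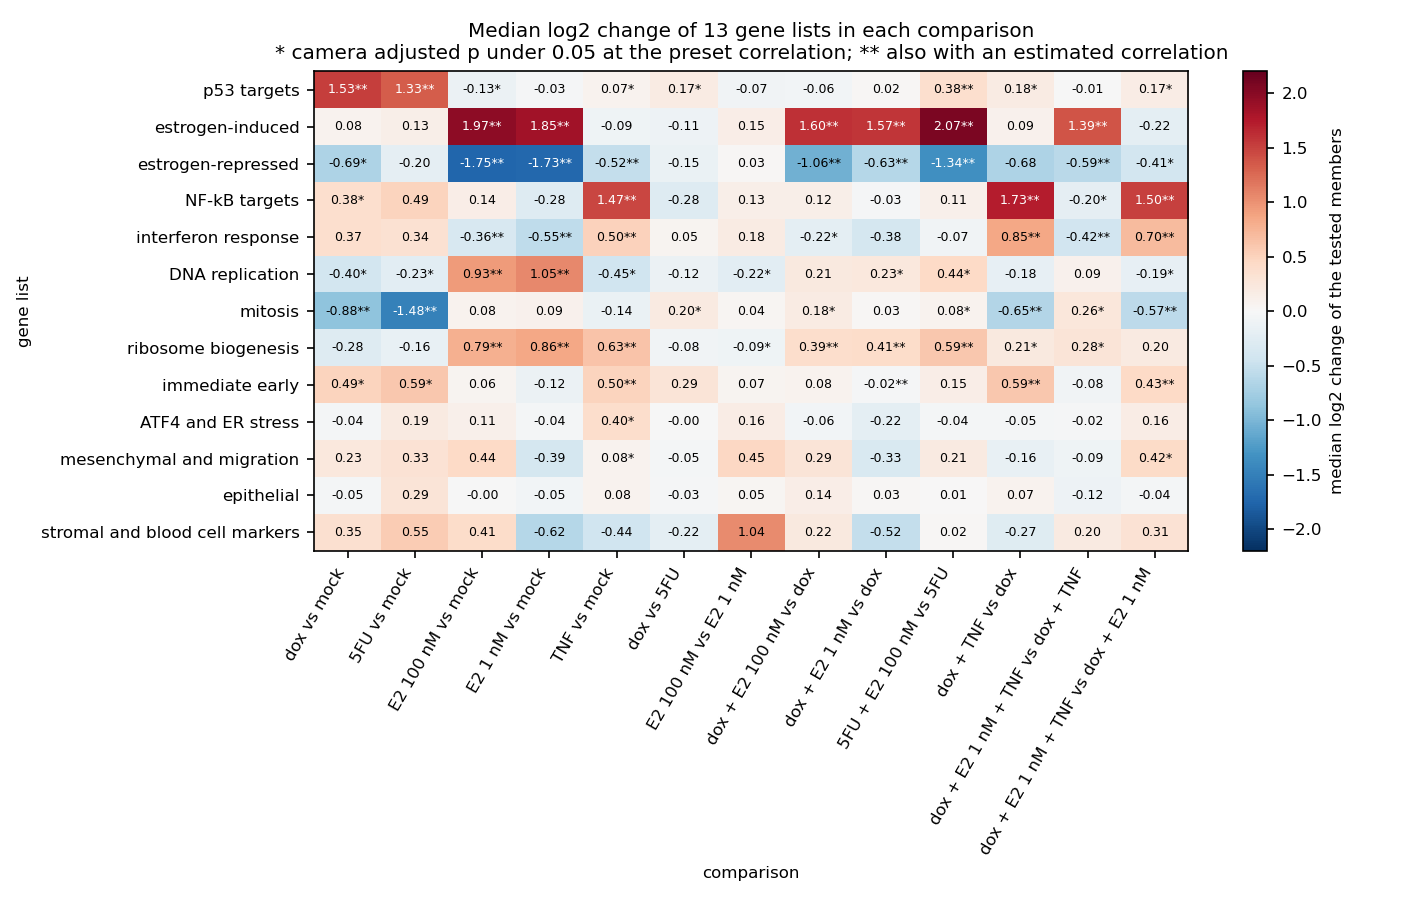
Median log2 change (colour) of 13 gene lists (y axis) in 13 comparisons (x axis). A star marks lists that passed the camera test with the preset correlation, and 2 stars those that passed also with an estimated correlation, such as p53 targets with doxorubicin at 1.53 and NF-kB targets with TNF at 1.47.

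Estradiol was added to doxorubicin at 100 nM and at 1 nM (n = 3 against 7 each) to ask whether hormone acted in cells with active p53. PGR rose 21.8-fold at 100 nM (4.45 ± 0.38, adjusted p = 5.6e-10) and 17.1-fold at 1 nM (4.09 ± 0.38, adjusted p = 4.4e-09). GREB1 rose 9.83-fold (3.30 ± 0.54) and 8.94-fold (3.16 ± 0.54), and MYC, low under doxorubicin, rose 8.62-fold (3.11 ± 0.31) and 5.78-fold (2.53 ± 0.31). CDKN1A was 0.11 ± 0.17 and 0.01 ± 0.17 from doxorubicin alone (adjusted p = 0.79 and 0.98), and GDF15 was −0.03 and 0.25 from it. FGFBP2 rose 34.2-fold and 30.3-fold, EGR3, a growth response gene, 32.7-fold at 100 nM, KLK10 19.7-fold at 100 nM, and MYB 13.5-fold and 12.7-fold. VAT1L fell 9.82-fold at 100 nM. TNFRSF11B fell 10.9-fold (−3.45 ± 0.34) and VTCN1 7.07-fold at 1 nM.

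Of 35 estrogen-induced genes 29 rose at 100 nM (33 adjusted over the list alone, median 1.60) and 26 at 1 nM (31 adjusted over the list alone, median 1.57). Of 11 estrogen-repressed genes 7 and 6 fell (8 each adjusted over the list alone), with EFNA1 down 2.64-fold at 100 nM. Of 19 ribosome biogenesis genes 8 and 5 rose (10 and 9 higher and 1 lower adjusted over the list alone), with medians of 0.39 and 0.41. These tests passed also with an estimated correlation, though for ribosome biogenesis at 1 nM not with the scan day as a block (adjusted p = 0.076 with an estimated correlation). Of 26 DNA replication genes 0 and 1 rose in limma (0 and 0 adjusted over the list alone), with medians of 0.21 and 0.23. The latter passed with the preset correlation (adjusted p = 0.23 with an estimated correlation), and with the block its median was 0.06. Of 24 mitosis genes 2 rose at 100 nM (4 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation) and 0 at 1 nM. Of 23 interferon response genes 1 and 2 fell (1 lower, then 1 higher and 6 lower adjusted over the list alone), and the test passed at 100 nM with the preset correlation (adjusted p = 0.069 with an estimated correlation). Of 19 immediate early genes 3 rose at each dose, with FOS up 4.20-fold and 3.19-fold, and at 1 nM the test passed upward although the median was −0.02 (adjusted p = 0.013 with an estimated correlation). Of 40 p53 targets 0 rose and 2 fell at 100 nM and 1 rose and 1 fell at 1 nM. NF-kB targets had 0 and 1 changed, epithelial genes 1 and 2, mesenchymal genes 2 and 1, ATF4 genes 0 and 0, and VWF rose 5.61-fold and 7.06-fold. In all, 1125 genes changed at 100 nM, 581 higher and 544 lower, and 1319 at 1 nM, 558 higher and 761 lower, against 661 higher and 452 lower with quantile normalization. In the fit with a scan day block 1106 and 973 passed, 900 and 771 of them shared. Within scan day 1 the 100 nM dose gave 130, and within scan day 3 the 1 nM dose gave 991.

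The effects of estradiol with and without doxorubicin were compared by the departure of the combination from the sum of the single-agent log2 changes. As a list, DNA replication genes fell short of that sum, although few passed singly. At 1 nM the list members MCM10 (−1.43 ± 0.27, adjusted p = 0.01), MCM2 (−1.24 ± 0.24, adjusted p = 0.012), MCM7 (−1.01 ± 0.21) and CDC6 (−1.22 ± 0.25, adjusted p = 0.019 each) fell short of the sum. For MCM10 the change was −1.50 with doxorubicin, 1.55 with estradiol and −1.38 with both. The pro-apoptotic gene BMF exceeded the sum at 100 nM (2.70 ± 0.42, adjusted p = 0.0018) and 1 nM (2.87 ± 0.42, adjusted p = 0.00062), as did TP53INP1 (1.94 ± 0.28 and 2.23 ± 0.28) and BTG2 (1.89 ± 0.32 and 2.09). The kinase gene SGK1 fell short, by −2.34 ± 0.39 at 100 nM and −2.08 at 1 nM. PGR and GREB1 departed by 0.07 and 0.17 at 100 nM (adjusted p = 1.0 each) and CDKN1A by 0.73 and 0.67 at the 2 doses (adjusted p = 0.58 and 0.35).

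Of 26 DNA replication genes 0 passed at 100 nM in limma (0 higher and 15 lower adjusted over the list alone), with a median of −0.74, and 4 were lower at 1 nM (18 adjusted over the list alone), with a median of −0.85. Both list tests passed with an estimated correlation (adjusted p = 0.002 and 0.00086), and within the scan days the medians were −0.98, −0.56 and −0.77. The estrogen-repressed list had 1 gene higher at each dose (2 and 5 adjusted over the list alone, medians 0.60 and 0.71) and also passed (adjusted p = 7.3e-06 and 4.2e-05 with an estimated correlation). Ribosome biogenesis genes had 0 changed at either dose and medians of −0.21 and −0.41 (adjusted p = 0.092 and 0.01 with an estimated correlation). The p53 list had 2 higher at each dose (4 and 1 adjusted over the list alone), a call with the preset correlation alone (adjusted p = 0.24 and 0.075 with an estimated correlation). At 1 nM the immediate early list passed (1 higher, adjusted p = 0.026 with an estimated correlation). Mitosis genes at 100 nM and interferon response and epithelial genes at 1 nM, with 0 members past the limma threshold, passed with the preset correlation alone (adjusted p = 0.29, 0.087 and 0.14 with an estimated correlation). In the estrogen-induced list 0 of 35 genes departed in limma at either dose (0 and 2 adjusted over the list alone), with medians of −0.11 and −0.13. At 100 nM 19 genes departed, 14 higher and 5 lower, and at 1 nM 73, 50 higher and 23 lower. The scan day block gave 58 and 284 genes, among them all 19 and 73. Within scan day 1 the 100 nM dose gave 0 genes by limma, with 1240 at an unadjusted p under 0.05 over all arrays, and within scan day 3 the 1 nM dose gave 75. Estradiol at 1 nM raised 344 genes both alone and in doxorubicin (25 if independent) and lowered 373 (40.8), and 5 went opposite ways. At 100 nM the numbers were 352 (19.4), 342 (17.4) and 1.

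**Figure D4:**
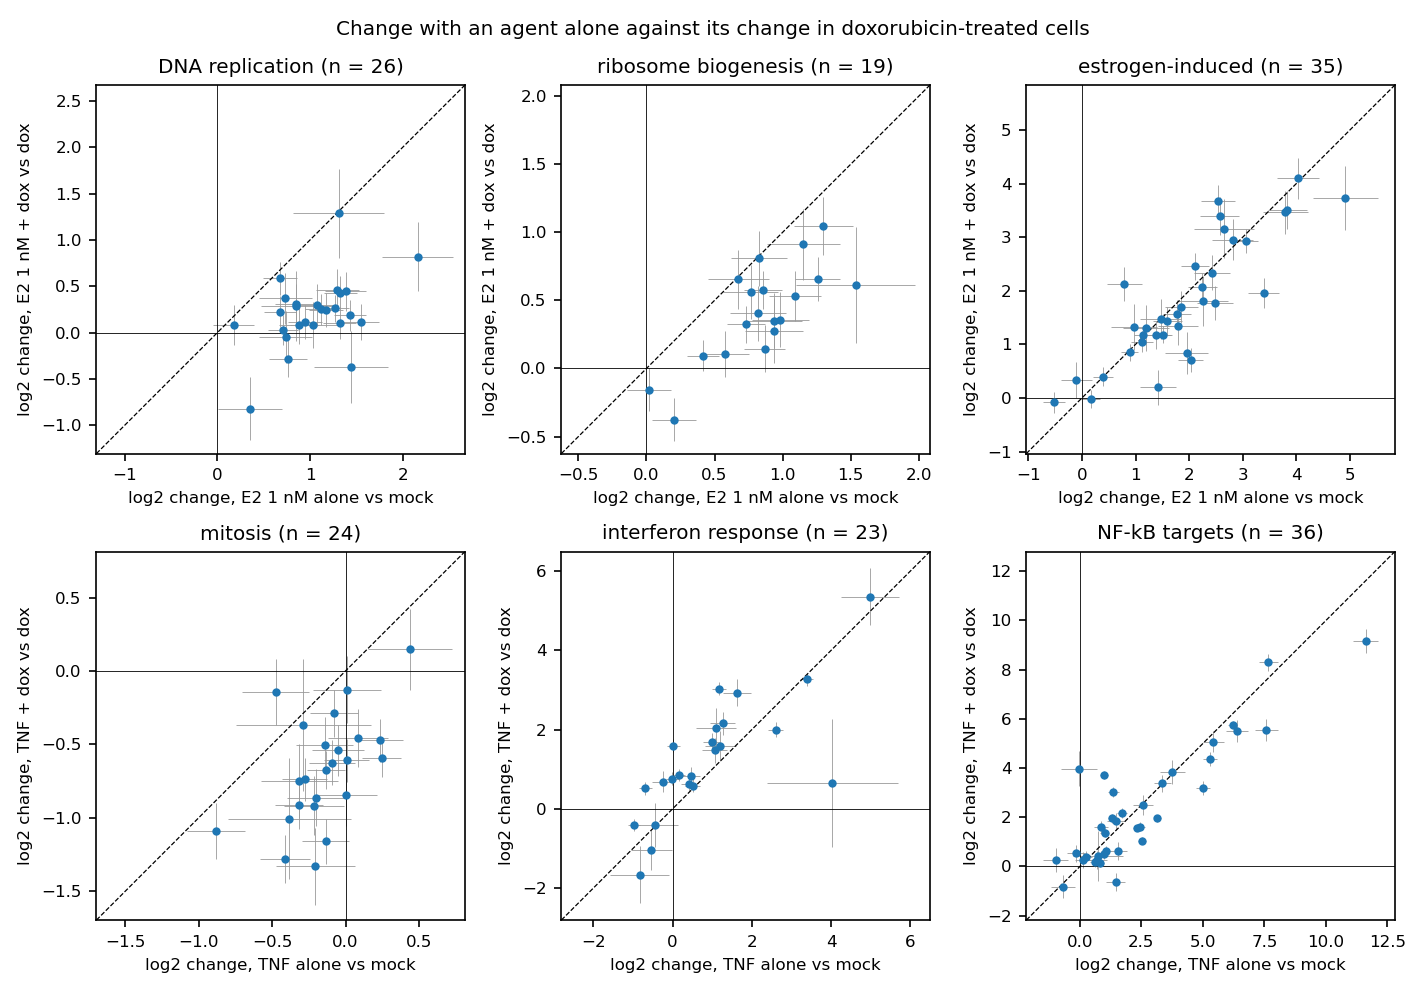
Log2 change of the genes of 6 lists when an agent was given alone (x axis) and in doxorubicin (y axis), with bars for standard errors and a dashed line of equality. The top panels are DNA replication, ribosome biogenesis and estrogen-induced genes with 1 nM estradiol, and the bottom panels mitosis, interferon response and NF-kB genes with TNF; the median of DNA replication genes was 1.05 alone and 0.23 in doxorubicin.

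Some genes differed in the combination of doxorubicin and estradiol from each agent given alone, in the same direction. At 100 nM there were 148, 63 higher and 85 lower, and at 1 nM 404, 157 higher and 247 lower. The potassium channel gene KCNF1 was higher by 3.18 than doxorubicin and 1.98 than estradiol at 100 nM, and by 3.26 and 2.43 at 1 nM. FGF18 was higher at both doses as well, and FOS at 100 nM by 2.07 and 1.97. CA5A, higher at 100 nM by 1.90 and 3.41, did not pass with the scan day as a block. TGFB2, the gene of a growth factor, was lower than with either agent at 100 nM (−2.29 and −2.36) and 1 nM (−2.07 and −2.39), as was TNFRSF11B (−1.93 and −2.83, then −3.45 and −3.76). Among estrogen-induced genes RET was higher at 100 nM, and RET, CXCL12, CTSD and SLC7A5 at 1 nM. With the block 182 and 373 genes passed. Within scan day 1 the 100 nM dose gave 16, and within scan day 3 the 1 nM dose gave 347.

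Estradiol at 100 nM was added to 5-fluorouracil (n = 3 each) to ask the same of a second drug. PGR rose 9.93-fold (3.31 ± 0.45, adjusted p = 8.8e-06), from −4.50 ± 0.63 (SD) to −1.19 ± 0.66, and GREB1 5.79-fold (2.53 ± 0.64, adjusted p = 0.024). FOS rose 13-fold (3.70 ± 0.27, adjusted p = 1.0e-10). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose 3.92-fold (1.97 ± 0.40, adjusted p = 0.0027). CDKN1A was 0.61 ± 0.20 and MDM2 0.67 higher (adjusted p = 0.12 and 0.46). FGFBP2, UGT2B11 and PGLYRP2 rose 20.5-fold, 16.1-fold and 15.4-fold, while VAT1L, PSCA and BMF fell 7.20-fold, 6.24-fold and 5.36-fold. Of 35 estrogen-induced genes 27 rose (29 adjusted over the list alone, median 2.07), of 11 estrogen-repressed genes 7 fell (9 adjusted over the list alone, median −1.34), and of 19 ribosome biogenesis genes 4 rose (10 adjusted over the list alone, median 0.59). Of 40 p53 targets 2 rose, PMAIP1 and GADD45A (1.88-fold), and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.38. The tests of these 4 lists passed also with an estimated correlation (p53 targets, adjusted p = 0.035).

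Of 26 DNA replication genes 3 rose after 5-fluorouracil with estradiol (5 adjusted over the list alone, median 0.44), among them MCM6, MCM7 and MCM2 at 0.82, 0.81 and 0.77, a call with the preset correlation (adjusted p = 0.057 with an estimated correlation). Mitosis genes had 0 changed in limma and a median of 0.08 (adjusted p = 0.38 with an estimated correlation). Immediate early genes had 1 higher and 1 lower (3 and 3 adjusted over the list alone), VWF rose 1.49 log2 units, and NF-kB, interferon response, ATF4, mesenchymal and epithelial lists had 0 changed members each. In all, 609 genes changed, 321 higher and 288 lower. The scan day block gave 921, including those 609, and within scan day 1 the number was 152. Estradiol raised 283 genes alone and in 5-fluorouracil (10.71 if independent) and lowered 235 (9.2).

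The combination departed from additivity in 2 genes, both p53 targets. BTG2 exceeded the sum by 2.55 ± 0.35 (adjusted p = 0.00085) and TP53INP1 by 1.82 ± 0.30 (adjusted p = 0.013). For BTG2 the change from mock was 1.60 with 5-fluorouracil, −1.81 with estradiol and 2.35 with both, and for TP53INP1 it was 1.23, −2.57 and 0.47. CDKN1A departed by 1.23 ± 0.26 (adjusted p = 0.31) and PGR by −1.06 (adjusted p = 1.0). Of 40 p53 targets these 2 were higher (7 adjusted over the list alone), with a median of 0.54 and within-day medians of 0.40 and 0.64 (adjusted p = 1.1e-05 with an estimated correlation). Medians were 0.37 for estrogen-repressed genes, 0.27 for interferon response genes and −0.47 for DNA replication genes, each with 0 members past the threshold in limma (adjusted p = 0.0017, 0.008 and 0.036 with an estimated correlation). In all 542 genes had an unadjusted p under 0.05. With the scan day as a block 2 genes passed, and within scan day 1 limma called 0. Beyond both agents there were 97 genes, 27 higher and 70 lower. They included PMAIP1 (1.97 and 1.95 higher), FOS (3.70 and 1.22 higher) and TNS3, a focal adhesion gene (−2.25 and −2.58). With the block 182 genes passed, and within scan day 1 the number was 4.

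TNF was added to doxorubicin (n = 3 against 7) to ask how NF-kB acts in cells with active p53. ICAM1 rose 53.7-fold (5.75 ± 0.18, adjusted p = 8.2e-22), NFKBIA 3.06-fold (1.62 ± 0.18, adjusted p = 5.6e-08) and TNFAIP3 33.6-fold (5.07 ± 0.43). CD83, an immune cell surface gene, rose 13.2-fold (3.72 ± 0.17) and RIGI, which encodes an RNA sensor, 8.16-fold (3.03 ± 0.17). Mitosis genes fell, HMMR 2.24-fold and KIF20A 2.43-fold. GDF15 rose 2.03-fold (adjusted p = 0.00016) and TP53 1.92-fold (0.94 ± 0.24, adjusted p = 0.0045), while CDKN1A was 0.06 higher (adjusted p = 0.84). PGR was lower, no longer well above background (adjusted p = 0.0011). UBD rose 1421-fold, LTB 568-fold, SERPINA3 393-fold, IL32 314-fold, S100A8 169-fold and CFB 74.7-fold. DDIT4L fell 11.9-fold, OVOL2 9.04-fold and PMP22 8.98-fold.

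Of 36 NF-kB targets 24 rose (25 adjusted over the list alone), with a median of 1.73, and PLAU rose 18.4-fold. Of 23 interferon response genes 17 rose (18 higher and 3 lower adjusted over the list alone), with a median of 0.85, or 1.16 over those above background in both groups, and PSMB9 rose 9.62-fold. Of 24 mitosis genes 16 fell (19 adjusted over the list alone, median −0.65), and of 19 immediate early genes 8 rose (10 adjusted over the list alone, median 0.59). These 4 tests passed also with an estimated correlation (mitosis, adjusted p = 0.0097). Among 40 p53 targets 9 rose and 2 fell (10 and 3 adjusted over the list alone), and of 19 ribosome biogenesis genes 5 rose, calls with the preset correlation (adjusted p = 0.11 each with an estimated correlation). DNA replication genes had 2 higher and 3 lower, estrogen-induced genes 4 and 7, estrogen-repressed genes 1 and 6 (2 and 7 adjusted over the list alone), and ATF4 genes 2 and 2 (2 and 4 adjusted over the list alone). Mesenchymal genes had 5 and 1, epithelial genes 4 and 4 (5 and 4 adjusted over the list alone), and VWF rose 2.34 log2 units. In all, 4459 genes changed, 1881 higher and 2578 lower. With the scan day as a block 4052 passed, 3300 of them shared, and within scan day 3 the number was 3973. TNF raised 904 genes alone and in doxorubicin (115 if independent) and lowered 1106 (286), and 31 went opposite ways. Blocked by scan day, the raised and lowered numbers were 811 and 858.

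Doxorubicin and TNF departed from additivity in 385 genes, 269 higher and 116 lower. CD83 exceeded the sum by 2.75 ± 0.25 (adjusted p = 1.6e-08), with 0.41 for doxorubicin, 0.98 for TNF and 4.13 for both. RIGI exceeded it by 1.85 ± 0.24 and IRF7, an interferon regulator gene, by 1.57. SLC52A3, a riboflavin transporter gene, exceeded it by 5.15 ± 0.39 (adjusted p = 2.6e-10). The inducible nitric oxide synthase gene NOS2 exceeded it by 4.95. TCIM (−3.75), PTAFR (−2.75) and AREG (−2.21) fell short. Among p53 targets GADD45A (−2.0 ± 0.30, adjusted p = 0.00016), TNFRSF10B (−1.17, adjusted p = 0.0025) and GDF15 (−1.11 ± 0.29, adjusted p = 0.044) fell short of the sum, although GDF15 was higher in the combination, 3.08 above mock, than with each agent, at 2.05 and 2.14. HMMR (−1.03 ± 0.22, adjusted p = 0.011) and AURKA (−0.84 ± 0.19, adjusted p = 0.014), both mitosis genes, were lower than the sum. ICAM1 departed by −0.47 and CDKN1A by −0.56 (adjusted p = 0.46 and 0.29).

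Of 23 interferon response genes 3 were higher than the sum (7 adjusted over the list alone, median 0.41), and of 24 mitosis genes 2 were lower (12 adjusted over the list alone, median −0.54). Both tests passed with an estimated correlation (adjusted p = 0.01 each). Of 36 NF-kB targets 3 were higher and 4 lower (4 and 9 adjusted over the list alone, median −0.33), with NFKBIE at −1.47 and SOD2 at −1.20, and this test did not pass. The ATF4 list had 1 lower, PSAT1 (−1.34; 1 higher and 5 lower adjusted over the list alone), a call with the preset correlation (adjusted p = 0.15 with an estimated correlation). Ribosome biogenesis genes had 0 passing and a median of −0.21 (adjusted p = 0.088 with an estimated correlation). With the scan day as a block 930 genes passed, including those 385, and within scan day 3 the number was 417. Beyond both agents there were 2012 genes, 917 higher and 1095 lower. They included 16 of 24 mitosis genes, all lower, 9 of 36 NF-kB targets, 9 of 23 interferon response genes and 7 of 40 p53 targets, all higher. The cytokine receptor gene IL3RA was higher than with doxorubicin and TNF (4.76 and 3.97), and SLITRK6 was lower (−2.78 and −2.90). With the block 2152 passed, and within scan day 3 the number was 2070.

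The combination of doxorubicin, 1 nM estradiol and TNF was compared with doxorubicin and TNF (n = 3 each) to find what estradiol adds, and with doxorubicin and estradiol (n = 3 each) to find what TNF adds. Estradiol raised PGR, not well above background without it (adjusted p = 5.7e-09) and GREB1 5.84-fold (2.55 ± 0.64, adjusted p = 0.032). FGFBP2 rose 19.8-fold, and the keratin genes KRT15 and KRT13 rose 16.6-fold and 14.1-fold. The antiviral gene OAS1 fell 3.00-fold (adjusted p = 0.036), OASL 2.63-fold and the cytokine gene IL1B 4.65-fold (adjusted p = 0.038). ICAM1 was −0.44 and NFKBIA −0.19 from doxorubicin and TNF (adjusted p = 0.64 for ICAM1). TNF raised ICAM1 32.3-fold (5.01 ± 0.21, adjusted p = 1.1e-17), NFKBIA 2.76-fold and TNFAIP3 28.7-fold over doxorubicin and estradiol. UBD rose 1050-fold, LTB 413-fold and CCL2 73.6-fold, and IL32, not well above background without TNF, was higher (adjusted p = 2.7e-16), while KCNJ8 fell most (−2.97). HMMR fell 1.85-fold (adjusted p = 0.0016), and CDKN1A was 0.01 and 0.06 from the respective pairs (adjusted p = 1.0 and 0.98).

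For estradiol added to doxorubicin and TNF, 21 of 35 estrogen-induced genes rose (28 adjusted over the list alone, median 1.39), 3 of 11 estrogen-repressed genes fell (5 adjusted over the list alone, median −0.59) and 3 of 23 interferon response genes fell (5 adjusted over the list alone, median −0.42). These 3 tests passed also with an estimated correlation (interferon response, adjusted p = 0.00023). NF-kB targets, mitosis genes and ribosome biogenesis genes had 0 changed in limma, with medians of −0.20, 0.26 and 0.28 (adjusted p = 0.15, 0.16 and 0.083 with an estimated correlation). Immediate early and mesenchymal genes had 1 higher each, and p53, DNA replication, ATF4, epithelial and stromal lists had 0. For TNF added to doxorubicin and estradiol, 22 of 36 NF-kB targets rose (25 adjusted over the list alone, median 1.50), 10 of 23 interferon response genes rose (13 adjusted over the list alone, median 0.70), 6 of 24 mitosis genes fell (11 adjusted over the list alone, median −0.57) and 1 of 19 immediate early genes rose (2 adjusted over the list alone, median 0.43). These 4 tests passed also with an estimated correlation (mitosis, adjusted p = 0.0052). Mesenchymal genes had 3 higher, p53 targets 2 higher, estrogen-repressed genes 1 higher and 3 lower, and DNA replication genes 0 changed, calls with the preset correlation (adjusted p = 0.088, 0.16, 0.055 and 0.35 with an estimated correlation). Estrogen-induced genes had 2 higher and 1 lower, epithelial genes 2 lower, ATF4 genes 1 higher, and ribosome and stromal lists 0.

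Estradiol changed 405 genes in doxorubicin and TNF, 236 higher and 169 lower, and TNF changed 1103 in doxorubicin and estradiol, 630 higher and 473 lower. With the scan day as a block 716 and 1715 passed, including those 405 and 1103, and within scan day 3, where all 9 arrays were scanned, 911 and 2116. Estradiol and TNF departed from additivity in doxorubicin in 13 genes, 4 higher and 9 lower. SERPINA3 fell short by −2.06 (adjusted p = 0.0098), with 1.84 for estradiol, 8.62 for TNF and 8.40 for both, and the coagulation inhibitor gene TFPI2 by −2.41 ± 0.29 (adjusted p = 3.4e-05). IL1R2, a decoy receptor gene, exceeded the sum by 2.87. NPY1R (−2.56) and ENOX1 (−1.68) did not pass with the block, under which 20 genes passed, 11 of them shared, and within scan day 3 the number was 23. ICAM1 departed by −0.73 (adjusted p = 0.59). The immediate early list passed downward with a median of −0.20 (adjusted p = 0.03 with an estimated correlation), and NF-kB, interferon response, DNA replication and ribosome lists with the preset correlation alone (adjusted p = 0.17, 0.17, 0.60 and 0.44 with an estimated correlation). In 58 genes the triple combination lay beyond both pairs, 33 higher and 25 lower. RAPGEFL1 and the apoptosis inhibitor gene BCL2, both estrogen-induced, were higher, as was the transglutaminase gene TGM2 (1.97 and 2.52). BMF (−1.72 and −2.41) and SPDEF, an epithelial transcription factor gene (−1.09 and −1.60), were lower. With the block 122 genes passed, and within scan day 3 the number was 184.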

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

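The tests of a difference between scan days for the DNA replication and mitosis patterns were chosen after the result was seen.

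As a list, DNA replication genes had a smaller change with estradiol in doxorubicin than without, though 0 of them passed singly at 100 nM and 4 at 1 nM. Scan days are argued against as the whole cause, since the list's within-day median departure nearest 0 was −0.56. So are compressed log ratios on doxorubicin arrays, which stay open as a part. The 291 other genes that 100 nM estradiol raised at least 2-fold on days 1 and 2 were compared on day 3. Their median change was 1.48 alone and 1.13 in doxorubicin, the list's 0.79 and 0.07. Median departures were −0.34 (quartiles −0.77 and 0.12) and −0.77. A fall of genes of like brightness is excluded, as 0% of 10000 random lists matched on signal had a lower median (lowest −0.28, list −0.85). No biological explanation was tested, and the pattern was found and tested on the same data.

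As a list, mitosis genes had a larger downward change with TNF in doxorubicin than with TNF alone. Scan days cannot be the whole cause, since the median was −0.56 within scan day 3, which held all 3 arrays of the combination, nor can a single array, since leaving out any 1 left −0.52 to −0.61. A fall of genes of like brightness is excluded, as 0% of the random lists were lower (lowest −0.39, list −0.54). No biological explanation was tested, and a lower share of dividing cells in these cultures stays open, since no cell counts were used here.

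The TP53 transcript signal was lower with 5-fluorouracil. It was −1.80 and −2.41 within scan days 1 and 2, which argues against a difference between scan days, and leaving out 1 array gave −1.51 to −2.07, which argues against a single array. The array has 1 probe for the gene, so a fault of the probe, such as a shift between transcript ends, could explain it and stays open.

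Departures from additivity are differences between the effects of an agent in the presence and absence of another, tested directly. They numbered 19 for doxorubicin and 100 nM estradiol, 73 for doxorubicin and 1 nM estradiol, 2 for 5-fluorouracil and estradiol, 385 for doxorubicin and TNF, and 13 for estradiol and TNF in doxorubicin. A sample far from the others was mock replicate 1, whose 75th percentile signal was 1942 (the others 1003 to 1322, n = 6). The other was doxorubicin replicate 4, where GREB1 was −3.80 (the others −1.44 to 0.05, n = 7). Chance sets apart a sample in about 1 in 20 groups, and 28 sets were tested.

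Other splits of the samples were counted for each result, with the real split included. Chance can be excluded for doxorubicin against mock (1 of 100 splits as large, 10051 genes against 4590 for the highest other). So it can for 1 nM estradiol (1 of 84, 2580 and 1765) and TNF (1 of 84, 4516 and 2519) against mock. The same holds for doxorubicin against 5-fluorouracil (1 of 100, 8466 and 6782) and TNF added to doxorubicin (1 of 100, 4459 and 3477). For 5-fluorouracil (1 of 84, 8155 and 4790) and 100 nM estradiol (1 of 84, 1715 and 360) against mock the splits ignored the pairs, so chance is left open. It is also open for 100 nM estradiol added to doxorubicin (3 of 100, 1125 and 4086). For 1 nM (3 of 100, 1319 and 2529) the share was under 0.05, but the highest other called more genes than the real split. None of these splits respected the scan day, so they cannot exclude it. The highest other split followed the scan day in 6 of these comparisons. It set apart mock replicates 1 to 3, from scan days 1 and 2, for 1 nM estradiol and TNF against mock (2090 and 3196 genes for the real split with the scan day as a block). It set apart arrays of scan days 1 and 2 for doxorubicin against 5-fluorouracil (8716 with the block) and for 1 nM estradiol and TNF added to doxorubicin (973 and 4052). For 100 nM estradiol added to doxorubicin it set apart the 3 doxorubicin arrays of day 3 (1106). That 4086 is several times 1125 points to the scan day as a structure of the samples. Where replicate numbers pair samples, the real split was the 1 as large among those that part all pairs, against highest others of 7997 (64 splits) for doxorubicin, 726 (8) for 5-fluorouracil, 148 (8) for 100 nM estradiol, 1 (8) when added to doxorubicin and 0 (4) when added to 5-fluorouracil. With 8 or 4 such splits no share under 0.05 is possible, so for these 4 comparisons chance is not excluded.

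With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. As large were 2 of 10 for the estradiol doses (1 and 1), 2 of 10 for estradiol added to 5-fluorouracil (609 and 1754, the latter setting apart 3 arrays of scan day 1, within which the real comparison gave 152), 1 of 10 for estradiol added to doxorubicin and TNF (405 and 2), and 1 of 10 for TNF added to doxorubicin and estradiol (1103 and 1). For departures from additivity, chance can be excluded for estradiol and TNF in doxorubicin (1 of 100, 13 and 3). It cannot for 5-fluorouracil and estradiol (8 of 100, 2 and 7). Doxorubicin with 1 nM estradiol had 1 of 100 (73 and 3) and with TNF 1 of 100 (385 and 46). With 100 nM it had 2 of 100 (19 and 27) here and 2 of 100 (148 and 1014) beyond both. These splits ignore the pairs, so chance is left open. For genes beyond both it can be excluded for the triple combination (1 of 100, 58 and 26). It cannot for doxorubicin with 1 nM estradiol (5 of 100, 404 and 2998) or TNF (2 of 100, 2012 and 2807). There the highest put 3 doxorubicin arrays of days 1 and 2 in place of the combination (real split with the block, 373 and 2152). Nor can it for 5-fluorouracil with estradiol (6 of 100, 97 and 4211). There the highest put the 3 arrays of estradiol alone (182 with the block). For doxorubicin with 100 nM estradiol it put 3 arrays of scan days 1 and 2 there (182 with the block).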

How the results depend on the processing

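Normexp on raw medians and the fit without scan day 2 were added after the data were seen; normexp on mean signals was not run, as the files lack that column. For 862 results of named genes, 8502 values under the alternatives had the same direction and side of the threshold. In 871 values (462 results) the gene no longer passed the threshold (weaker). In 39 (19) a gene passed that had not before (stronger), and 30 (28) were reversed. On leaving out arrays 8514 were the same, 598 weaker and 10 stronger. List counts moved in 523 values (2051 did not) and on leaving out arrays in 265 (2348). For every change listed here the cause was not tested; the model of the compared groups alone has fewer arrays to estimate the spread. With no filter (32842 genes) or the filter of 20 arrays (21038 genes), no count of changed genes moved over 1.5-fold. Arrays had 47.4 to 77% of probes well above background, which limits what can be measured for the rest.

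Counts follow one order: doxorubicin, 5-fluorouracil, 100 nM and 1 nM estradiol and TNF against mock; doxorubicin against 5-fluorouracil; the estradiol doses; in doxorubicin 100 nM and 1 nM estradiol; estradiol in 5-fluorouracil; TNF in doxorubicin; estradiol, then TNF, in the triple combination. With normexp on medians they were 3550, 3700, 476, 123, 229, 2679, 0 (limma; 4292 unadjusted in the main analysis), 99, 42, 47, 699, 10 and 46. Departures from additivity for doxorubicin with 100 nM, 1 nM estradiol, 5-fluorouracil with estradiol, doxorubicin with TNF, and estradiol with TNF were 0, 0, 0, 2 and 0. Beyond both, for the first 4 of these combinations and the triple, were 3, 3, 1, 252 and 1.

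Reversed with normexp on medians, none past the threshold, were VIM (−0.55), MDM2 (−0.41), TNFAIP3 (−0.55) and ICAM1 (−0.51) for doxorubicin; VEGFD (−0.0931), NOLC1 (0.16), FOSL1 (−0.53), ITGA5 (−0.21) and MDM2 (−0.20) for 5-fluorouracil; ICAM1 (−1.23), SNAI1 (−0.56) and VWF (−0.17) for 100 nM estradiol; PLAUR (0.39) between the drugs; PAX3 (0.59), BLNK (0.31), IFIT1 (0.32) and STAT2 (0.15) for 1 nM estradiol in doxorubicin; VAT1L (0.0564) in the triple combination; the departure of SEC14L2 (0.60); and beyond both IFNLR1 (0.0210), CCL20 (−0.38), IL1B (−0.11) and VAT1L (0.0564). With quantile normalization FBL (−0.13), NPM1 (−0.14) and ICAM1 (−0.61, past the threshold) reversed for 5-fluorouracil, and with the authors' table FBL (−0.13) and NPM1 (−0.14). With the mean of probes CCND1 (−0.0464) and ESR1 (0.000174, from −0.69) did.

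With the compared groups alone, 5-fluorouracil gave 3506, then 892, 1694, 2400, 4951, 1147, 282, 352, 35, 1965 and 226 up to estradiol in the triple combination; departures 5, 27, 0, 100 and 7; beyond both 50, 188, 17, 1003 and 100. With the slide as a random block, 100 nM estradiol gave 3343, estradiol in 5-fluorouracil 1031 and the triple comparisons 896 and 2032; departures 174, 585, 8, 1671 and 58; beyond both 226, 666 and 236 for the estradiol pairs and 167 for the triple. With the scan day as a block, estradiol in 5-fluorouracil gave 921 and the triple comparisons 716 and 1715; departures 58, 284, 930 and 20; beyond both 182 and 122. Without scan day 2 the doses gave 0, the triple comparisons 676 and 1705, departures 11 and 116, and beyond both 97 (100 nM) and 125 (triple). Quantile normalization gave 2 for the doses and 26 departures for estradiol with TNF, and the authors' own values gave 2 and 25.

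With the replicate number as a block, where numbers pair arrays the counts were 12006, 8778 and 2347 for doxorubicin, 5-fluorouracil and 100 nM estradiol, and 883 and 895 for estradiol added to each. In the other comparisons the numbers were not found to pair arrays, and counts were 8953 for 1 nM estradiol, 10660 for TNF, 3364 for the doses, 7026 and 8905 for 1 nM estradiol and TNF in doxorubicin, and 682 and 1657 for the triple comparisons. For results that join comparisons, some of them paired, there were departures of 45, 243, 970 and 1830; beyond both 1125 (1 nM), 176 (5-fluorouracil) and 110 (triple).

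Leaving out 1 array gave 8975 to 10364 for doxorubicin and 6409 to 9255 for 5-fluorouracil. For 100 nM estradiol the range was 1048 to 1830 (1048 and 1115 without its replicates 1 and 2), for 1 nM 1450 to 3836 (1501, 1450 and 1581 without its 1, 2 and 3), for TNF 2992 (its 2) to 5935, for the drugs 7185 to 9154, and for the doses 0 (100 nM replicate 1 or 1 nM replicate 2) to 1. In doxorubicin 100 nM estradiol gave 575 (its 1) to 1708 (doxorubicin 1), 1 nM 623 to 2368 (662, 623 and 673 without its 1, 2 and 3, 2368 without doxorubicin 5), and TNF 2528 to 5500 (2804 and 2528 without its 1 and 3). Estradiol in 5-fluorouracil gave 381 (its 3) to 1041 (5-fluorouracil 3). The triple comparisons gave 218 (doxorubicin with TNF 2) to 298, with 252 without triple 3, and 700 (triple 1) to 1129.

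Departures ranged over 10 to 39 for 100 nM estradiol (39 without doxorubicin 1, 12 and 10 without estradiol 2 and 3, 11 without the combination's 2), and 31 to 111 for 1 nM (111 without mock 4, 37, 32 and 31 without estradiol 1, 2 and 3, 46, 31 and 47 without the combination's 1, 2 and 3). They ranged over 1 (estradiol 1, 5-fluorouracil 2 or combination 1) to 3 with 5-fluorouracil, 144 to 490 with TNF (175 and 240 without TNF 2 and 3, 148 and 144 without the combination's 1 and 3), and 6 to 22 for estradiol with TNF (22 without doxorubicin 5, 8 and 6 without doxorubicin with estradiol 2 and 3, 6 without doxorubicin with TNF 3, 7 without triple 1). Beyond both gave 75 to 175 for 100 nM (98 without estradiol 1, 95 and 75 without the combination's 2 and 3), 181 to 617 for 1 nM (617 without doxorubicin 5, 208, 181 and 225 without the combination's 1, 2 and 3), 42 to 228 for 5-fluorouracil (63 and 228 without its 1 and 3, 42 without the combination's 3), 1040 to 2233 for TNF (1111 and 1040 without the combination's 1 and 3) and 29 to 50 for the triple (29 without doxorubicin with TNF 2, 30 and 36 without triple 1 and 2).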

Other observations

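MYC, which drives cell growth, moved with 3 of the agents. It was −3.13 with doxorubicin, 1.67 and 1.49 with 100 and 1 nM estradiol and 1.48 with TNF, and added to doxorubicin these gave 3.11, 2.53 and 2.30. The potassium channel gene KCNJ8 fell with TNF in all 3 backgrounds, by 3.12 in mock, 3.39 in doxorubicin and 2.97 in doxorubicin with estradiol, and OVOL2, an epithelial transcription factor gene, by 1.60, 3.18 and 2.46. VWF, a marker of endothelium, rose with estradiol (1.45 and 1.39) and TNF (2.13). No other member of its list of stromal and blood cell genes rose in these 3 comparisons.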
